A study of Mus musculus with 4 samples.

How the data were processed

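The samples were 4 libraries of mRNA from bone marrow cells of wild-type C57BL/6 mice, cultured in DMEM with fetal bovine serum and L929 supernatant per the labels' protocols. They covered unstimulated cells and cells given 100 nM Pam3Cys4 for 5 h, each without shRNA and with shRNA against lncRNA-COX2, with 1 library per group as the labels give it. The titles of the libraries without shRNA carry the abbreviation EV, which the labels do not explain. Whether those cells carried a control construct is therefore not known, and each shRNA ratio is against cells that the labels describe only as without shRNA. Per the labels' protocols, libraries were made with an Illumina mRNA kit and read at 50 bp. Per the submitters' processing notes, reads were processed with CASAVA 1.8, aligned with TopHat to NCBIM37 and counted with HTSeq, and the versions of TopHat and HTSeq, the annotation release and the strand setting are not given in the sources used here. The deposited values are read counts per gene, made by the authors with HTSeq, and were checked to be whole numbers with the HTSeq summary lines present.

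Each table held the same 37681 gene IDs, of which 32642 were matched to a symbol and biotype in GENCODE vM21. This reference is on another genome build than the counts, so only names and biotypes were taken from it and no coordinates. IDs without a symbol, 5039 in number, held 0.717 to 0.915% of gene reads. Gene reads per library were 47385277 (no shRNA, unstimulated), 51979051 (no shRNA, Pam3Cys4), 65826838 (shRNA, unstimulated) and 59400238 (shRNA, Pam3Cys4). In the same order, 33.5, 34.4, 32.5 and 32.6% of all totals in the tables named no gene, and alignments to several places alone made up 28.7, 29.9, 27.0 and 27.3% of all totals. Genes with close copies elsewhere in the genome were therefore undercounted.

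Counts were scaled with edgeR 4.0.16 TMM factors (1.10, 0.972, 1.01 and 0.924) in R 4.3.3. For each of 4 pairs of libraries, the ratio of scaled counts was computed for genes with at least 5 CPM in the higher library, with an exact 95% interval from the conditional binomial distribution. Focus genes and genes looked up by name are given also below this filter. A gene counted as at least 2-fold apart when its ratio reached 2 or 0.5 and the interval excluded 1. A count of 0 was replaced by a floor of 3 counts per library for the ratio, in list medians too. For single genes with such a 0, the text gives the lower 95% limit of the fold as a bound. With 1 library per group no p-value was given for these ratios. The ratio of ratios, the stimulation ratio with shRNA over that without, was computed for genes with at least 10 counts in each library and 5 CPM in the highest, with an interval from the delta method.

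The only test across genes was an edgeR quasi-likelihood F test of an additive model with shRNA and stimulation, on genes with at least 5 CPM in at least 2 libraries, with Benjamini-Hochberg adjustment at 0.05. It had 1 residual degree of freedom, 3.76 prior degrees of freedom and a common biological coefficient of variation of 0.137. Any interaction entered its error. For each effect it took the 2 states of the other factor as repeats, so its p-values do not cover spread between separately prepared cultures. Agreement was computed only between comparisons that share no library, as Pearson and Spearman coefficients and as overlaps beside the product of the set sizes over the number of genes.

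The choice of comparisons, filters, 31 gene lists with 611 genes, rules for named genes and other settings to try was made before the data were examined. The lists covered focus genes, inflammatory cytokines, chemokines, interferon-stimulated and interferon gamma genes, NF-kB feedback, immediate early genes, the TLR pathway, macrophage effectors, alternative activation, MHC class II, eicosanoids, cholesterol synthesis, LXR and efflux, glycolysis, cell cycle, p53 targets, the unfolded protein response, heat shock, macrophage markers, 7 other cell types, and mitochondrially encoded, ribosomal protein, housekeeping and histone genes. Of the listed genes 593 were matched. Each list's median was placed among 10000 random lists of the same size matched on expression in 20 bins, as description only. Of the marker lists, 1 granulocyte gene, 1 dendritic cell gene and 1 mast cell gene also belong to another list, and Lcn2, Tfrc and Hdc can be expressed by macrophages too.

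Named genes were all focus genes, per comparison the 10 higher and 10 lower genes whose interval bound nearest to 1 lay farthest from it, the 10 smallest p-values per direction in the additive test, and up to 4 members of each list with the largest absolute ratio, with fewer printed. Other genes named in the text, including Y-linked genes, their X-linked relatives, Ifnb1, genes read in 1 shRNA state and list members outside these ranks, were chosen after their values were seen. The targeted lncRNA and some genes within these ranks are not reported here.

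Alternatives were DESeq2 1.42.0 size factors (0.930, 0.907, 1.20 and 1.00), library totals alone, CPM minimums of 1 and 20, no filter, thinning of all libraries to 47385277 reads, the mean in place of the list median, and for the additive test DESeq2 Wald and limma 3.58.1 voom. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

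The methods were tested on simulated data. The additive test recovered 98 of 98 genes changed 2-fold and 98 of 98 changed 4-fold, with 9 false calls among 205. The simulated coefficient of variation was 0.1, below the 0.137 of the data, and no interaction was simulated. The pairwise ratios called 100 of 100 genes changed 3-fold in the stimulation and shRNA comparisons tested and 0 unchanged genes. Intervals covered the true ratio for 94.7 to 95.1% of genes. These libraries, also used for the lists below, were simulated with Poisson error only, without spread between cultures. Of 200 unchanged lists 12 fell outside percentiles 2.5 to 97.5, and 20 of 20 shifted lists lay above.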

Results

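Transcript levels were measured by mRNA sequencing in wild-type C57BL/6 mouse bone marrow cells grown with L929 supernatant, a source of the macrophage growth factor M-CSF. The cells were left unstimulated or stimulated with 100 nM Pam3Cys4, a lipopeptide sensed by TLR2 together with TLR1, and carried or did not carry an shRNA against lncRNA-COX2. There was 1 library for each of the 4 groups. The libraries held 47385277 and 51979051 gene reads without shRNA (unstimulated and Pam3Cys4) and 65826838 and 59400238 with shRNA, over 17213, 17235, 17267 and 16916 genes. Fth1, the ferritin heavy chain, took the most reads in each library, 2.38, 3.34, 2.86 and 3.35% in the same order. With 1 library per group, no difference between groups was checked against replicates, and every interval below covers counting error only.

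The level of lncRNA-COX2 itself was not analysed here, so the strength of the knockdown was not determined. Ptgs2, which encodes the prostaglandin-producing enzyme COX-2 and lies next to the targeted RNA, was 63.3-fold higher after Pam3Cys4 without shRNA (95% counting interval 58.8 to 68.3) and 59.6-fold higher with shRNA (53.5 to 66.5). Its level was 13.5 CPM (counts scaled to library size) and 857 CPM without shRNA, and 5.10 and 304 CPM with shRNA. Ptgs2 was thus 2.65-fold lower with shRNA in unstimulated cells and 2.82-fold lower after Pam3Cys4, and the ratio of its stimulation folds was 0.941 (0.826 to 1.07). Pla2g4a, whose product releases the arachidonic acid that COX-2 uses, was also lower with shRNA, 2.33-fold in unstimulated cells and 1.77-fold after Pam3Cys4. The additive test below takes the 2 stimulation states as repeats of each shRNA state, so its shRNA p-values do not cover spread between cultures. In the additive test over all 4 libraries, Ptgs2 rose with stimulation (log2 5.94, standard error 0.14, adjusted p 0.0006) and fell with shRNA (log2 -1.45, standard error 0.12, adjusted p 0.00224).

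Other immune genes chosen in advance split into a group that was lower and a group that was higher with shRNA. These genes were chosen partly from knowledge of the published report on these samples and are not independent evidence. Il6 had 0 counts in both unstimulated libraries and 971 and 114 counts after Pam3Cys4. By the lower limits it was at least 271-fold higher after stimulation without shRNA and at least 36.9-fold higher with shRNA. After Pam3Cys4, Il6 was 9.26-fold lower with shRNA. Il23a, below the 5 CPM filter, was 6.99-fold lower with shRNA after Pam3Cys4 (135 and 21 counts), and Tlr1, the receptor chain for the ligand used, was 15.5-fold lower in unstimulated cells and 12.2-fold lower after Pam3Cys4. Il1b was 4952-fold higher after stimulation without shRNA (2692 to 10327) and 1964-fold higher with shRNA (1257 to 3262). Tnf was 15.7-fold and 45.1-fold higher after stimulation, so that with shRNA it was 2.04-fold lower in unstimulated cells and 1.41-fold higher after Pam3Cys4. Higher with shRNA, in unstimulated cells and after Pam3Cys4, were the chemokine genes Ccl5 (4.27-fold and 4.14-fold) and Cx3cl1 (22.6-fold and 53.6-fold), the receptor gene Ccrl2 (6.30-fold and 7.04-fold), and the interferon-stimulated genes Irf7 (27.6-fold and 17.3-fold), Isg15 (57.0-fold and 20.2-fold), Oas1a (12.3-fold and 10.3-fold), Oas2 (46.2-fold and 28.8-fold) and Ifi204 (41.2-fold and 18.2-fold). Hnrnpab and Hnrnpa2b1, which encode RNA-binding proteins, did not pass the additive test for shRNA (adjusted p 0.121 and 0.235). Of the 15 genes of this list that were tested, 8 rose and 3 fell with shRNA, also 8 and 3 adjusted over the list alone, and 11 rose with stimulation, or 14 adjusted over the list alone.

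**Figure D1:**
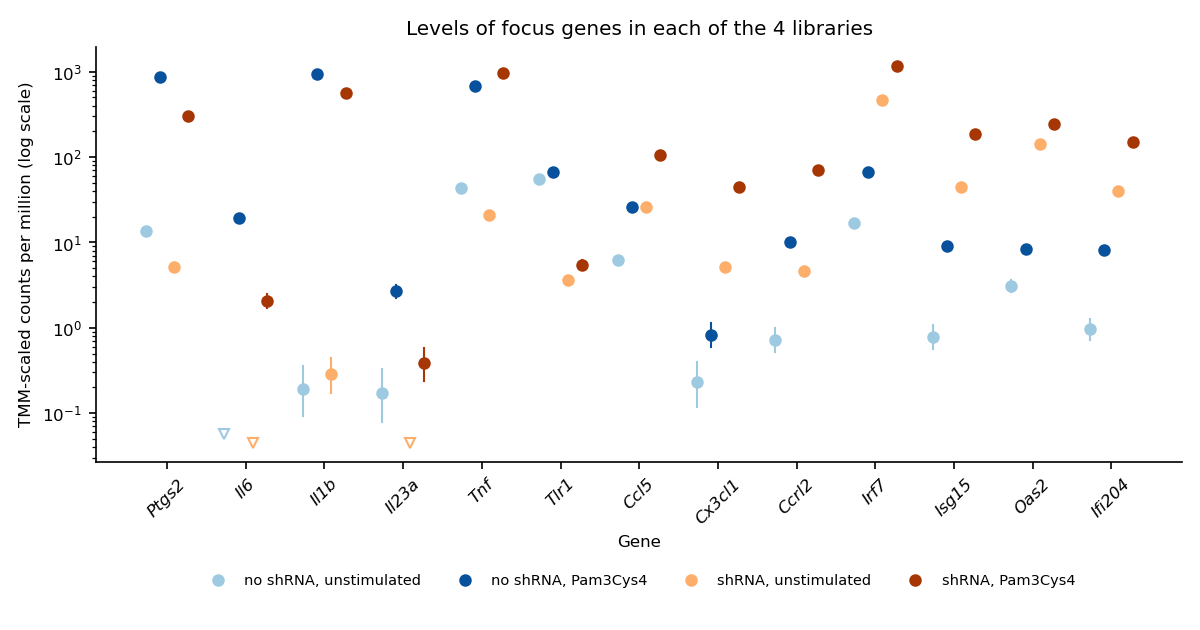
Levels of focus genes in each of the 4 libraries, with exact counting intervals. Open triangles mark libraries with 0 counts, drawn at the floor of 3 counts.

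Pam3Cys4 without shRNA brought on the inflammatory response known for TLR2 ligands. Transcripts of the neutrophil growth factor Csf3, of interleukin-1 and of the chemokine Cxcl2 went from near absence to high levels, while cell cycle genes were lower. Of 9555 measured genes, 676 were at least 2-fold higher and 622 at least 2-fold lower. With library totals as the only scaling these counts were 541 and 898, and the median log2 ratio of all genes was then -0.185.

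Cytokine and chemokine genes were among those with the largest ratios. Of 14 measured inflammatory cytokine genes, 13 were at least 2-fold higher and 0 lower, with a median log2 ratio of 4.14. Csf3, which drives neutrophil production, went from 3 to 24561 counts (log2 ratio 13.04, interval 11.50 to 15.32), Il1a was 1412-fold higher, and Csf2 went from 2 to 874 counts (log2 ratio 8.82, 6.96 to 11.87). Of 15 chemokine genes, 13 were at least 2-fold higher and 1 lower, with a median of 3.60. Cxcl2 was 1403-fold higher and Cxcl3 at least 155-fold higher. Among 28 macrophage effector genes, 26 were at least 2-fold higher and 0 lower (median 2.81), including Acod1, which makes itaconate (113-fold), and Nos2, the inducible nitric oxide synthase (197-fold). Lcn2, an iron-withholding protein, was 730-fold higher, and the matrix protease gene Mmp3 went from 1 to 880 counts (log2 ratio 9.83, 7.34 to 15.13). The medians of these 3 lists lay at percentile 100 of 10000 expression-matched random lists.

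Regulators of the response were higher as well. Of 26 genes of NF-kB feedback, 18 were at least 2-fold higher and 0 lower (median log2 ratio 1.90, percentile 100), among them Nfkbiz (71.4-fold), Traf1 (38.1-fold) and Zc3h12a (34.1-fold), which restrain or redirect NF-kB signalling. Of 24 immediate early genes, 13 were higher and 2 lower (median 1.12, percentile 100), with Ier3 10.1-fold higher. The interferon-stimulated list had 26 of 42 genes at least 2-fold higher and 0 lower (median 1.41, percentile 100), with Ifit1 21.9-fold, Rsad2 16.5-fold and Ifit3 12.5-fold higher. Genes typical of interferon gamma had a median of 0.47, with 5 of 12 higher, among them the guanylate-binding protein gene Gbp2 (19.9-fold), whose family has near-identical copies. In the TLR pathway list, 5 of 19 genes were higher and 0 lower (median 0.26), including the co-receptor Cd14 (6.31-fold), Irak2 (3.87-fold) and Tlr2 itself (2.81-fold).

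Among genes lower after Pam3Cys4, Slco2b1, an organic anion transporter, was 22.4-fold lower, Zfp395 13.4-fold, Kank2, a regulator of the cytoskeleton, 9.72-fold and Nanos1 9.04-fold. Zfyve28 was 11.2-fold lower and Cxcr4, the receptor that holds cells in the marrow, 11.2-fold. All 32 cell cycle genes had negative log2 ratios (median -0.67, percentile 0), and 9 were at least 2-fold lower, with cyclin E1 (Ccne1) 3.38-fold, Mcm7 2.66-fold and E2f1 2.65-fold lower.

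Pam3Cys4 with shRNA went with higher levels of many genes that were also higher without it. Il1b, Csf3 and Il1a were again among the genes with the largest ratios, now with Nos2, and Nos2 and Saa3 had larger ratios than without shRNA. Of 9601 measured genes, 605 were at least 2-fold higher and 339 lower, or 494 and 466 with library totals alone, where the median log2 ratio of all genes was -0.118. Csf3 was 1324-fold, Il1a 1150-fold, Lcn2 723-fold and Cxcl2 298-fold higher. Nos2 was 1346-fold, Saa3, an acute-phase protein, 129-fold, Gbp2b, of a family with near-identical copies, 107-fold and Socs3, an inhibitor of cytokine receptor signalling, 71.8-fold higher. Adora2a, an adenosine receptor gene, went from 1 to 309 counts (log2 ratio 8.55, interval 6.06 to 13.86). Lower were Cxcr4 (11.6-fold), the sulfate transporter Slc26a11 (7.31-fold), Shisa9 (7.21-fold) and Lpin1, a lipid phosphatase (6.74-fold).

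By list, 12 of 15 inflammatory cytokine genes (median log2 ratio 2.32), 12 of 13 chemokine genes (3.96) and 20 of 25 macrophage effector genes (2.84) were at least 2-fold higher with shRNA present, and 0 lower. NF-kB feedback genes had 22 of 27 higher (1.55), with Nfkbiz 64.8-fold and Traf1 52.4-fold, and immediate early genes 12 of 22 (1.10). Interferon-stimulated genes had 34 of 52 higher (1.44), including Ifi205 (37.0-fold), Mx1 (14.3-fold) and Ifit1 (8.78-fold). The interferon gamma list had 13 of 17 higher (1.35), with Gbp2 22.9-fold. The TLR pathway list had 5 of 22 higher (0.36), with Cd14 5.43-fold and Tlr2 4.2-fold. These 8 medians lay at percentiles from 99.7 to 100. Cell cycle genes were again low, with a median of -0.33 (percentile 0.02) and 4 of 32 at least 2-fold lower.

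The stimulation ratios in the 2 shRNA states, which share no library, were similar gene by gene. Over 9142 genes measured in both, Pearson r was 0.865 and Spearman rho 0.791, a description since genes are not independent replicates. Of 598 and 509 genes at least 2-fold higher, 374 were shared, against 33.3 expected for independent sets. Of 534 and 294 genes lower, 216 were shared, against 17.2. Opposite directions at 2-fold were seen for 3 genes: Il1rl1, the receptor for interleukin-33, was higher without shRNA and lower with it, and Maf and Parp8 the reverse.

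**Figure D2:**
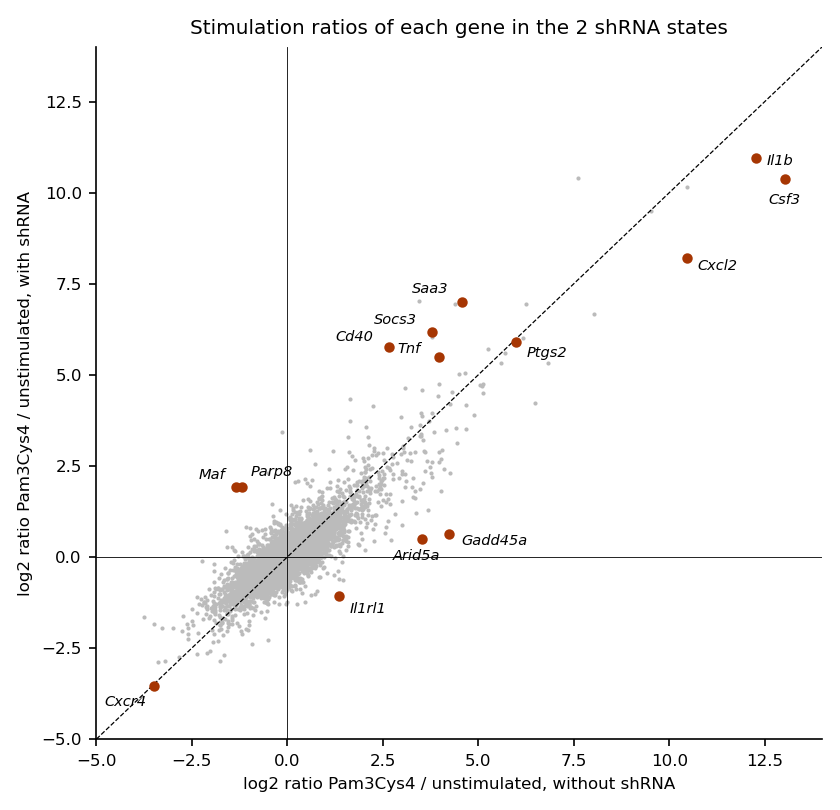
Stimulation ratios of each gene without and with shRNA. The dashed line marks equal ratios.

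The shRNA against lncRNA-COX2 went with a raised interferon programme in unstimulated cells, and with genes that were read almost only with or only without it. Of 9651 measured genes, 676 were at least 2-fold higher and 465 lower with shRNA, or 593 and 556 with library totals alone. Of 50 interferon-stimulated genes, 49 were at least 2-fold higher and 0 lower (median log2 ratio 3.80, percentile 100), and the other was Ifi27. Cmpk2 was 131-fold, Lgals3bp 99.1-fold and Oasl2 96.8-fold higher, and Ddx60 went from 1 to 628 counts. Of 14 genes typical of interferon gamma, 12 were higher and 0 lower (median 2.86, percentile 100), among them Gbp9 (25.4-fold), Gbp3 (20.1-fold) and Irgm1 (13.8-fold), members of families with near-identical copies. The endosomal receptors Tlr3 (8.38-fold) and Tlr8 (12-fold) were higher too, although the TLR pathway list as a whole had a median of only 0.35, with 3 of 21 genes higher and 1 lower.

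Outside the interferon genes, several transcripts were near absent on 1 side. Higher with shRNA in unstimulated cells were Eya1 (0 and 8317 counts, at least 1763.5-fold) and the neuropeptide gene Npy (at least 1050-fold). So were the ubiquitin ligase gene Nedd4 (at least 772-fold) and Tspan7, from 3 to 8029 counts (log2 ratio 11.03, interval 9.48 to 13.31). Lower with shRNA were the carbonic anhydrase gene Car2 (2772-fold), Ly86, an accessory protein of TLR-like receptors (3920 and 1 counts, log2 ratio -12.29) and Car12 (2667 and 2 counts). Of 6 alternative activation genes 1 was higher and 2 were lower: Arg1 was 292-fold and Mrc1 17.5-fold lower, and Tgm2 45.7-fold higher. The inflammatory cytokine list had 4 of 7 genes higher and 1 lower (median 1.45), with Csf1, the M-CSF gene, 15.3-fold higher. Chemokine genes were evenly split, 3 higher and 3 lower of 10 (median -0.06, and 0.00 with library totals alone), with Cxcl10 7.31-fold higher and Pf4 8.32-fold lower. Of 23 immediate early genes, 2 were higher and 5 lower (median -0.11), with Egr2 8.97-fold and Egr1 4.19-fold lower. The unfolded protein response list was lower, with a median of -0.41 (percentile 0), 2 of 19 genes at least 2-fold lower and Herpud1 3.29-fold lower.

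After Pam3Cys4 the interferon programme was again higher with shRNA, and several stimulated cytokine and chemokine transcripts were lower. Of 9702 measured genes, 873 were at least 2-fold higher and 541 lower, or 772 and 605 with library totals alone. Of 52 interferon-stimulated genes, 51 were higher and 0 lower (median log2 ratio 3.42, percentile 100), including Lgals3bp (77.0-fold), Ddx60 (74.0-fold) and Cmpk2 (54.9-fold), and of 17 interferon gamma genes 15 were higher and 0 lower (3.10, percentile 100), with Gbp9 45-fold and Gbp3 31.4-fold. Chemokine genes had a median of -0.68 (percentile 0), with 3 of 16 higher and 6 lower: Cxcl10 was 9.95-fold higher and Pf4 13.6-fold lower. Of 17 inflammatory cytokine genes, 5 were higher and 6 lower, with Csf2 158-fold lower and Il15 9.23-fold higher, and their median of 0.31 changed sign with the filter, so no direction was given for the list. Slpi, a secreted protease inhibitor, was 2126-fold lower and Car2 1891-fold lower. Npy (at least 1600-fold) and the endothelial lipase gene Lipg (2136-fold) were higher. Tlr3 was 21.7-fold higher, with 7 of 22 TLR pathway genes higher and 1 lower (median 0.37).

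The shRNA ratios in the 2 stimulation states, which also share no library, were close. Over 9339 genes, r was 0.929 and rho 0.762, with 520 shared genes at least 2-fold higher of 625 and 781 (52.3 expected) and 307 shared lower of 392 and 465 (19.5 expected). Opposite directions at 2-fold were seen for 4 genes: Arid5a was higher with shRNA only in unstimulated cells, and Cd40, Maf and Saa3 only after Pam3Cys4. The libraries with and without shRNA also differed in Y-linked genes, which were examined only after their values were seen: Ddx3y had 3 and 4 counts without shRNA against 921 and 1116 with it, Kdm5d 0 and 1 against 730 and 665, and Uty 1 and 0 against 320 and 334, while Eif2s3y had 3 and 6 against 0 and 0. Whether the shRNA comparisons also compare cells from different animals was not determined, and whether the cells without shRNA carried a control construct is not given in the labels.

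**Figure D3:**
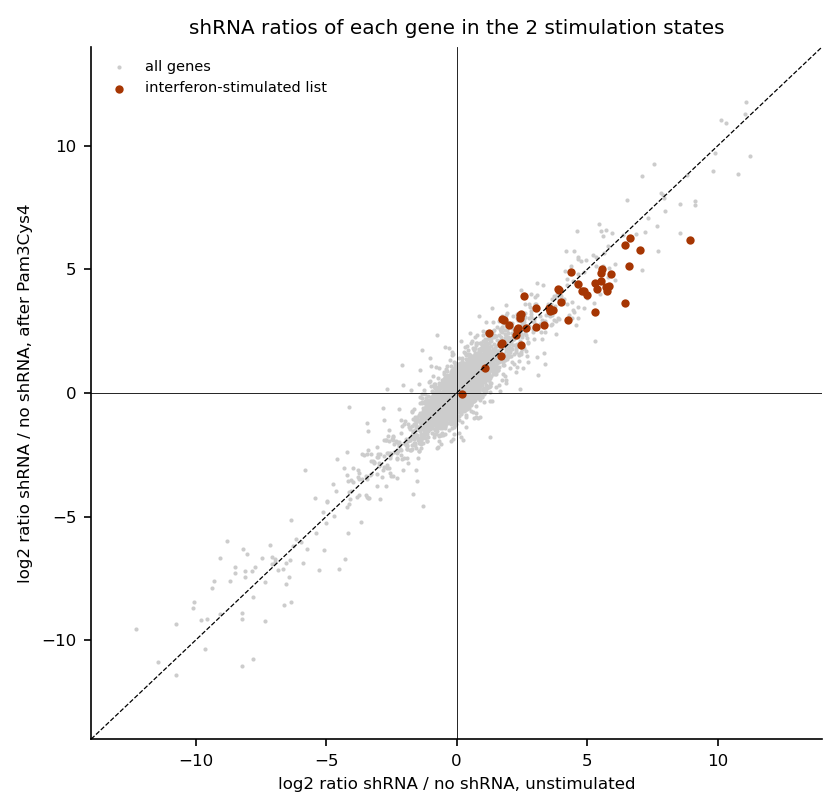
shRNA ratios of each gene in unstimulated cells and after Pam3Cys4, with the interferon-stimulated list marked.

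The measured stimulation folds differed by shRNA state for part of the genes. Each fold compares single libraries, so spread between libraries cannot be told apart from a true difference. Of 9857 genes with a ratio of ratios, 191 had a stimulation fold at least 2-fold larger with shRNA and 162 at least 2-fold smaller. With library totals alone, 233 were larger and 139 smaller. Genes with under 10 counts in any library had no ratio of ratios, which left out strongly stimulated genes such as Csf2 (2 and 874 counts without shRNA, 0 and 6 with it), Mmp3 (1 and 880 against 1 and 28) and Il6 (0 and 971 against 0 and 114). Larger with shRNA were Cntnap1 (11.9-fold, log2 3.58, interval 3.26 to 3.90), the transcription factor gene Maf (9.45-fold), the co-stimulatory receptor gene Cd40 (8.53-fold), Parp8 (8.69-fold) and Tnfrsf14 (7.03-fold). Smaller with shRNA were Baiap2l1 (17.8-fold), the stress gene Gadd45a (12.2-fold), Cish, an inhibitor of STAT5 signalling (14-fold), Myo1d (9.87-fold) and Tgm1 (13.1-fold). Arid5a, which stabilizes Il6 mRNA, was 8.21-fold smaller. By list, the median log2 ratio of ratios was -0.80 for inflammatory cytokines (percentile 0, 2 of 12 larger and 4 smaller), -0.31 for chemokines (percentile 0.26, 1 of 14 larger and 2 smaller) and -0.24 for interferon-stimulated genes (percentile 0, 4 of 47 larger and 10 smaller), against 0.53 for interferon gamma genes (percentile 100, but a mean of 0.29, positive in 10 of 16, 3 larger and 2 smaller), 0.30 for cell cycle genes (percentile 100, positive in 31 of 32) and 0.53 for mitochondrially encoded genes (percentile 100, positive in 8 of 9). It was 0.31 for NF-kB feedback genes, positive in 16 of 27.

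In the additive test, which used all 4 libraries and took any interaction as error, 1138 of 9559 genes rose and 1045 fell with Pam3Cys4, and 1171 rose and 828 fell with shRNA. The shRNA results of this test do not separate the shRNA from other fixed differences between the 2 sets of cells, as in Y-linked genes. With Pam3Cys4, Il1a (log2 10.33), Lcn2 (9.47), Ptgs2 (5.94), Nfkbiz (6.09) and the collagenase gene Mmp13 (5.66) rose. Cxcr4 (-3.51), Lpin1 (-2.79), Gpr162 (-2.54) and the RNA-binding protein gene Nanos1 (-3.02) fell. With shRNA, Tspan7 (11.08), Lipg (10.84), the spectrin gene Sptbn1 (7.96) and Adamts1 (9.29) rose, and Car2 (-11.12), Emp2 (-6.91) and the ceramide synthase gene Cers4 (-10.93) fell. All 26 macrophage effector genes tested rose with Pam3Cys4, also 26 adjusted over the list alone, as did 36 of 50 interferon-stimulated genes (44 adjusted over the list alone), 21 of 27 NF-kB feedback genes (23 adjusted over the list alone), 16 of 23 immediate early genes (19 adjusted over the list alone), 12 of 14 chemokine genes (12 adjusted over the list alone) and 11 of 12 inflammatory cytokine genes (12 adjusted over the list alone). Cell cycle genes fell, 13 of 32 (22 adjusted over the list alone). With shRNA, 49 of 50 interferon-stimulated genes rose (49 adjusted over the list alone) and 13 of 16 interferon gamma genes rose and 1 fell (15 and 1 adjusted over the list alone). Fewer members passed for shRNA among inflammatory cytokines (3 rose and 2 fell; 3 and 3 adjusted over the list alone), chemokines (4 and 6; 4 and 7 adjusted over the list alone), macrophage effectors (6 and 5; 8 and 5 adjusted over the list alone) and immediate early genes (4 and 6; 4 and 8 adjusted over the list alone). Of 19 unfolded protein response genes, 9 fell with shRNA and 0 rose (11 and 0 adjusted over the list alone).

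**Figure D4:**
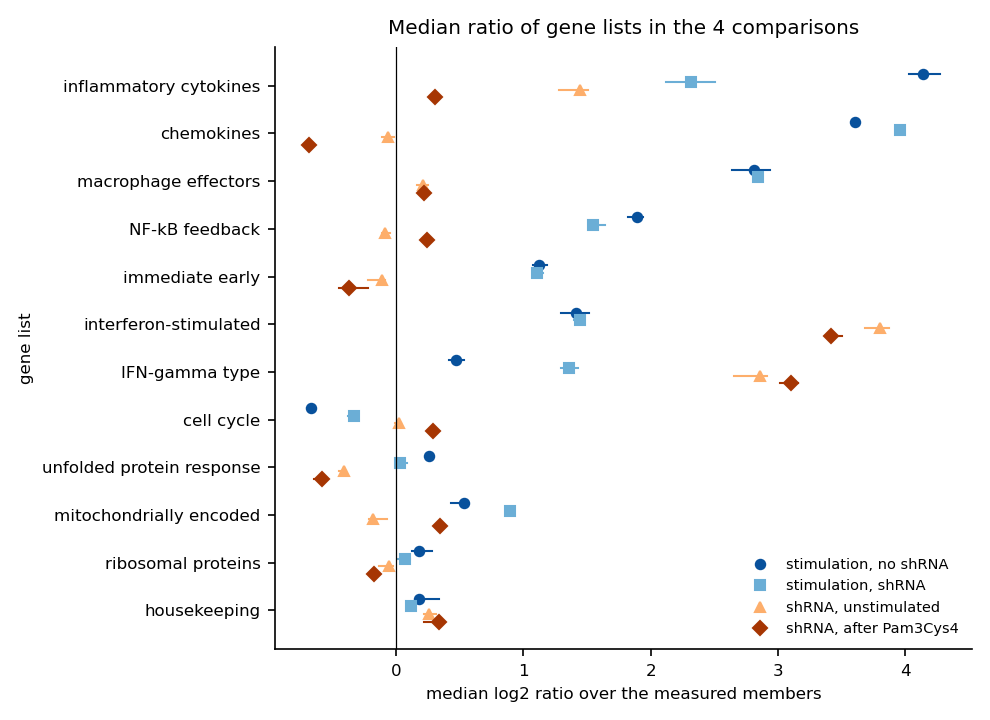
Median log2 ratio of gene lists in the 4 comparisons, with ranges from Poisson-resampled counts. Medians near 0 change sign with the scaling for several lists.

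Lipid and metabolic genes showed small list medians beside single large changes. In the eicosanoid list, 3 of 13 genes were higher and 3 lower with Pam3Cys4 without shRNA: Ptges was 4.64-fold higher and Ptgs1, the constitutive cyclooxygenase gene, 2.95-fold lower. With shRNA the list median was -0.45 in unstimulated cells (4 of 12 lower) and -0.24 after Pam3Cys4 (3 of 13 lower), with the prostacyclin receptor gene Ptgir 6.93-fold and 3.76-fold lower, and 5 of 13 genes fell in the additive test (5 adjusted over the list alone). Cholesterol synthesis genes stayed near 0, with medians from -0.04 to -0.18 over the 4 comparisons, and 1 of 23 rose and 6 fell with Pam3Cys4 (1 and 7 adjusted over the list alone). In the LXR and efflux list, the median was -0.04 without and -0.41 with shRNA for stimulation, and 0.24 for shRNA in both stimulation states, and the LXR alpha gene Nr1h3 was 15.7-fold and 16.2-fold higher with shRNA. Glycolysis genes had stimulation medians of 0.21 and 0.12, the latter changing sign with library totals, and 6 of 20 rose with Pam3Cys4, with the glucose transporter gene Slc2a1 2.88-fold higher without shRNA. Pfkfb3 was 2.18-fold higher with shRNA in unstimulated cells.

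Stress lists were mixed. Of 18 p53 target genes, 5 rose and 3 fell with Pam3Cys4 (5 and 5 adjusted over the list alone). After Pam3Cys4 without shRNA, the death receptor gene Fas was 11.5-fold higher, Sesn1 7.93-fold lower and Gdf15 6.54-fold higher. Heat shock genes had medians of 0.23 and 0.46 for stimulation, with Hspa1a 10.2-fold and its near-identical copy Hspa1b 7.71-fold higher with shRNA present. Macrophage marker genes had medians of 0.11 and 0.04 for stimulation, both negative with library totals alone, and 0.15 and 0.09 for shRNA. With shRNA, 3 of 24 were at least 2-fold higher and 2 lower in unstimulated cells, and 3 higher and 4 lower after Pam3Cys4. Mertk was 7.90-fold and 7.36-fold higher with shRNA, while the lowest log2 ratios of the list were -4.13 and -3.99. For stimulation, 4 of 23 were higher and 2 lower without shRNA, and 6 of 24 higher and 3 lower with it. Fcgr2b was 8.57-fold and 4.26-fold higher after Pam3Cys4. Mitochondrially encoded genes were higher with stimulation (medians 0.53 and 0.89), with 5 of 9 rising (8 adjusted over the list alone). Ribosomal protein genes had medians of 0.18 and 0.07, the latter negative with library totals alone, and Rpl3 was 2.70-fold and 4.05-fold lower with shRNA, while Rps6, which has near-identical copies, was 5.65-fold higher with shRNA after Pam3Cys4. Housekeeping genes had medians of 0.18 and 0.11 for stimulation, both negative with library totals alone, and 0.26 and 0.34 for shRNA, with B2m 2.13-fold higher in unstimulated cells. The histone list had only 3 measured genes, with shRNA medians of 0.69 and 0.47. Of the MHC class II list only Cd74 was measured, 2.29-fold and 1.73-fold higher after Pam3Cys4 and 4.33-fold and 5.75-fold lower with shRNA.

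Marker lists of other cell types were read mainly as levels, and were used for 1 test in the closing section. Summed CPM over the libraries without shRNA (unstimulated, Pam3Cys4) and with shRNA in the same order were 8.98, 91.0, 0.750 and 88.5 for granulocytes, carried by Lcn2 after Pam3Cys4 and by Cebpe (7.90 CPM) in unstimulated cells without shRNA, 0.403, 0.356, 0.315 and 0.219 for B cells, 11, 26.5, 14.6 and 17.4 for T and NK cells, and 7.98, 27.0, 1.05 and 3.77 for dendritic cells. They were 452, 567, 140 and 178 for erythroid cells, carried by Car2 and Tfrc without shRNA and by Tfrc with it, 0.710, 5.46, 1.19 and 16.7 for mast cells and basophils, carried by Hdc, and 2.26, 6.81, 2.27 and 5.68 for fibroblasts. The dendritic cell sums were thus lower with shRNA in both stimulation states. Of 3 measured granulocyte genes, 2 were at least 2-fold lower with shRNA after Pam3Cys4 and 0 higher (median log2 ratio -4.56, percentile 0.29), with Cebpe 80.4-fold and Mmp8 23.7-fold lower.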

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

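The tests weighed in this part, on marker lists, Ifnb1, Y-linked genes and their X-linked relatives, genes read in 1 shRNA state, and genes that rose with stimulation, were chosen only after the results were seen. The test on the relatives replaced an earlier 1 that was not able to separate the outcomes, and a second condition on the Y-linked test was dropped, both with the counts known. The scaling by library totals and the thinning to equal depth were planned.

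For 7 genes a difference between groups stood out, because the same contrast went opposite ways. The log2 stimulation ratios without and with shRNA were 1.36 and -1.08 for Il1rl1, -1.33 and 1.91 for Maf, and -1.19 and 1.93 for Parp8. The log2 shRNA ratios in unstimulated cells and after Pam3Cys4 were 1.27 and -1.77 for Arid5a, -1.34 and 1.75 for Cd40, -2.09 and 1.15 for Maf, -1.0 and 1.43 for Saa3, and -1.03 and 0.50 for Tnf. These differences were not tested, since each group was 1 library. Outside the counted genes, reads on no annotated gene made up 3.64% of all totals in the unstimulated shRNA library and 3.48% in the Pam3Cys4 shRNA library, above the 3.0 and 2.85% without shRNA. What these reads are was not tested.

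The first pattern weighed was the higher level of interferon-stimulated genes with shRNA. Cells of the 7 listed other types were examined through the marker lists. Their highest median level over members in a shRNA library was 0.0150 CPM, which argues against a large share of such cells. A few such cells would not move these medians, so a small population stays open. Only single genes such as Tfrc, Lcn2 and Hdc were abundant, and Hdc carried a mast cell sum of 16.7 CPM with shRNA against 5.46 without it after Pam3Cys4. Cell types without a list were not examined. With library totals alone the median log2 ratio was 3.68. The TMM factors of the 2 unstimulated libraries, 1.10 and 1.01, were too close for this alternative to decide on scaling. A scaling error shifts all genes alike, so it leaves the gap between the list and all genes unchanged. The unstimulated median was 0.024 over 9651 genes, near 0 through the scaling itself, against 3.80 for the list. These medians were -0.098 and 3.68 with library totals alone. The gap argues against scaling. Interferon beta made by the unstimulated shRNA cells cannot be told apart from other triggers, since Ifnb1 was 3.91-fold higher with an interval of 0.834 to 36.7. Loss of the targeted RNA, the biological explanation that the design gives, and an effect of carrying an shRNA as such stay open and untested. So does a fixed difference between the 2 sets of cells, which also differed in Y-linked genes. The labels do not say whether the cells without shRNA carried a control construct.

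The second pattern was the set of genes read in 1 shRNA state only. Different cells behind the 2 shRNA states may be the source. Of 4 Y-linked genes, 3 were at least 10-fold apart in both stimulation states, while Eif2s3y, near the floor, went the other way. These counts prompted the test, so they are no separate support. Xist, the X-inactivation RNA, was near absent in all 4 libraries, so no difference in sex was shown. Direct silencing by the shRNA through partial matches gives no genes absent without shRNA, of which there were 16, though indirect effects stay open, and for the 13 genes absent with shRNA it cannot be told apart from other causes, because there was no second shRNA. Reads shared between Y-linked genes and their X-linked relatives would keep each gene in proportion to its relative. Against this, the log2 ratio of gene to relative differed between the shRNA states by a median over 4 pairs of 7.24 or more. The median rests on Ddx3y, Uty and Kdm5d. For Eif2s3y, near the floor, the differences were -0.77 and -0.89, which do not argue against shared reads. Loss of the targeted RNA was not tested, and no value here separates it from a difference between cells for any shRNA comparison.

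The third pattern was stimulation folds that differ by shRNA state. Weaker receptor signalling in the shRNA cells, with Tlr1 low, cannot be told apart from an effect of the targeted RNA. No other ligand was used. The median log2 ratio of ratios of 1117 genes that rose with stimulation was -0.10, with members going both ways. This median cannot decide, since the additive test that chose the genes takes a fold differing by shRNA state as error. Genes with under 10 counts in any library were missing too. Of 3175 genes with both stimulation intervals above 1, at any fold, 42 had folds at least 2-fold larger and 89 at least 2-fold smaller with shRNA. Unequal depth was argued against by 203 genes with larger and 160 with smaller folds at equal depth, where the deposited depth gave 191 and 162. Spread between libraries cannot be told apart from a true difference, since the SD of 0.45 over genes had no replicate to compare with.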

How the results depend on the processing

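All alternatives in this part were planned. Of 100 values of counts, correlations and overlaps under alternatives, 75 stayed near their reported value (counts within 1.5 times, correlations within their interval), including all those under DESeq2 size factors, library totals alone, equal depth, the DESeq2 Wald test and limma-voom. Within this limit, library totals took genes lower for stimulation without shRNA from 622 to 898, and the share of higher genes from 52.1 to 37.6%. The counts of genes read in 1 state, chosen after the values were seen, stayed within it in all 18 values. Those for splits of the libraries other than by shRNA state were 0 throughout. The other 25 changed with the CPM minimum, which by its construction sets how many genes are measured.

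With a minimum of 20 CPM, genes at least 2-fold lower were 382 for stimulation without shRNA and 193 with shRNA. For shRNA, 424 were higher and 220 lower in unstimulated cells, and 571 higher and 325 lower after Pam3Cys4. The ratio of ratios had 114 higher. Shared genes were 126 lower for stimulation, and 317 higher and 142 lower for shRNA, with correlations of 0.885 and 0.923. With a minimum of 1 CPM, 526 genes were lower for stimulation with shRNA, 791 for shRNA in unstimulated cells and 893 after Pam3Cys4, and the ratio of ratios had 313 higher and 255 lower. Shared genes were 327 lower for stimulation and 540 lower for shRNA, with correlations of 0.842 and 0.921. With no filter, the additive test had 2013 genes higher and 1857 lower for stimulation and 2170 and 1874 for shRNA.

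Of 699 list medians under alternatives, 468 stayed within the counting range and 230 moved beyond it, 86 of these with library totals and 77 with the mean over members. The sign changed in 43, of which 20 with library totals and 14 with the mean over members: alternative activation in unstimulated cells (median 0.39, mean -0.85 for shRNA) and macrophage effectors (0.21 and -0.33, and 0.22 and -0.54 after Pam3Cys4) are examples. Among lists outside the middle 95% of random lists the sign changed in 1, the immediate early ratio of ratios, with a mean of 0.0019 against a median of -0.19, and the cause was not tested. Of 1980 single gene ratios 1695 stayed within the counting interval, 285 moved, and the sign changed in 19, in none of the ratios called at least 2-fold. Of 2658 additive results for single genes 2480 kept their side of the threshold, 174 passed it only under the alternative, and 4 passed it no longer, all with the DESeq2 Wald test.

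No paired analysis was possible because the labels give no pairing of libraries beyond their groups. Leaving out a library was not possible, since each group was 1 library and 3 libraries leave the additive model no residual degree of freedom. Depth limits the genes near the floor of 3 counts, such as Il6 and Eya1, to bounds.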

Other observations

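The tests on genes read in 1 state were chosen after the values were seen, as were all genes named in this part.

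Among genes higher after Pam3Cys4 in both shRNA states, the folds differed in both directions between these single libraries. With shRNA the log2 stimulation ratio was larger for Cd40 (2.67 without and 5.76 with shRNA), Saa3 (4.58 and 7.01), Socs3 (3.79 and 6.17) and the adenosine receptor gene Adora2b (3.80 and 6.03), and for Gpr84, a receptor for medium-chain fatty acids (3.08 and 4.64). It was smaller for Cish (6.67 and 2.86), the cystine transporter gene Slc7a11 (4.09 and 2.42), the kinase gene Pim1 (3.97 and 2.61), the interleukin-1 receptor antagonist gene Il1rn (4.01 and 2.68) and Acod1 (6.82 and 5.31). Il1rn and Acod1 were nonetheless higher with shRNA before and after stimulation, at 45.3 and 731 CPM without and 141 and 906 CPM with shRNA for Il1rn, and 11.9 and 1344 against 79.7 and 3171 CPM for Acod1.

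Genes with at least 5 CPM in both libraries of 1 shRNA state and at most 3 counts in each of the others numbered 29, against 0 for the split by stimulation and 0 for the crossed split. This limit leaves out Il6 and Cxcl3, with 0 counts in both unstimulated libraries but under 5 CPM after Pam3Cys4 with shRNA. Read only with shRNA were 16: Phyhip, Tnfrsf21, Eya1, Sel1l3, Npy, Plekha5, Col4a6, Pir, Plxna3, Fgfr1, Tbx20, Nedd4, Slc9b2, Kdm5d, Tspan7 and Fam189a2. Read only without shRNA were 13: Cers4, Stc2, Ly86, Iqgap2, Slco5a1, Tfcp2l1, Ambp, Car12, Arap2, Grk3, Zic2, Ccdc85c and Hectd2os.

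In the order unstimulated and Pam3Cys4 without shRNA and then with shRNA, Ifnb1 had 2, 28, 10 and 47 counts, and Xist 0, 2, 0 and 1. Of the X-linked relatives of the Y-linked genes, Ddx3x was at 249, 334, 259 and 317 CPM, Kdm5c at 195, 241, 195 and 223 CPM, Kdm6a at 32.0, 22.3, 32.5 and 27.0 CPM and Eif2s3x at 29.6, 45.5, 39.4 and 38.7 CPM.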
